A study of Caenorhabditis elegans with 12 samples.

How the data were processed

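RNA was sequenced from whole worms of 4 genotypes grown at 20 °C, with 3 samples of 100 worms each, collected 24 h after L4. Per the labels' protocols, 500 ng of total RNA entered a stranded mRNA library kit and libraries were read as pairs of 75 bp. The submitters' processing notes name STAR, featureCounts 1.5.1 and the build WBcel235; the STAR version and the strand setting of the counting are not given in the sources used here. The deposited values are whole-number counts of reads per gene, not normalized, as the authors' table holds them. All 12 columns were assigned to samples by their names, and the table has 0 rows that name no gene. Of 46739 genes, 21518 had no read in any library. Gene names and coordinates came from an annotation of WBcel235, release 115, and the gene name table holds 43720 identifiers. Because the strand setting is not stated, overlapping and antisense genes are uncertain. How reads that match several places were counted is not given either. Families of near-identical copies, such as the msp genes and hsp-16.1 with its copy, are therefore uncertain as well.

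Library totals were 30837773 to 48894725 counts. Every pair of replicates differed by more than counting error (chi-square per degree of freedom 3.61 to 17.98), and the labels call the samples biological replicates. Libraries that share a replicate number across groups were not more alike (median residual correlation 0 over 18 pairs), so the numbers were not used as pairs. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, leaving 15764, and scaled by TMM. One quasi-likelihood model with robust estimation was fitted to all 12 libraries, leaving 8 residual degrees of freedom, and 5 pairwise contrasts and the interaction were tested two-sided. Benjamini-Hochberg adjusted p-values below 0.05 were called. Standard errors are the absolute log2 fold change divided by the square root of the F statistic.

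31 gene lists were fixed before the data were examined, 30 of them with at least 5 measured members, and each was tested within a comparison by camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Every camera call was repeated with an estimated correlation and none was called then. fry, which tests a list without setting it against the other genes, was run beside it. It is quoted for some lists that camera did not call. Calls were also counted adjusted over the list alone. Named genes followed a rule fixed before the data were examined: daf-2, spr-3, spr-4 and hop-1 always, the 8 largest called rises and 8 largest called falls per pairwise comparison among genes with a gene name, a mean log2 CPM of at least 1 and groups that do not overlap, 6 of each sign for the interaction, and up to 4 called members of each list by absolute log2 fold change. rrn-3.1 was added after its values were seen, as was the ribosomal RNA share.

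Correlations of effects that share libraries were set beside 20 simulations of unchanged groups. Alternatives were RLE size factors, total counts, no filter, at least 1 CPM in 6 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, fits of only the groups compared, a test against a 1.5-fold change, an estimated correlation for the lists, and leaving out each of the 12 libraries. The models were tested on simulated counts with 200 changed genes: for daf-2 against N2, 97.0% of 4-fold and 67.2% of 1.5-fold changes were recovered among 15441 genes, and 6.8% of the calls were false. For the interaction 84.8% of 4-fold and 37.9% of 1.5-fold changes were recovered among 15440 genes, and 3.8% of the calls were false. Far more genes passed in the data, which makes the adjusted threshold less strict, so these shares need not hold there. Figures were drawn with matplotlib 3.10.9. No GC correction was made, since no genome sequence was used here.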

Results

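Gene expression was measured by RNA sequencing in whole Caenorhabditis elegans worms of 4 genotypes, with 3 biological replicates each. N2 is the wild-type laboratory strain. The daf-2 mutant carries a change in the gene of the insulin/IGF-1 receptor, a regulator of lifespan. The spr double mutant (spr-4;spr-3) carries changes in the genes of zinc-finger proteins related to the mammalian repressor REST. The remaining libraries are labelled spr-4;spr-3;daf-2 and are called the triple-labelled libraries here. Each sample held 100 worms collected 24 h after the L4 stage. Library totals ran from 30837773 to 48894725 counts, and 15764 of the 46739 genes in the count table were tested. The first principal component held 59.2% of the variance and the second 19.4%.

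The genes named in the genotypes were examined first. spr-3 (WBGene00005008, X, 4514093 to 4516895 in WBcel235) had 17.3 ± 1.06 CPM in N2, 17.5 ± 1.44 in daf-2, 9.22 ± 0.779 in the spr double mutant and 16 ± 1.24 in the triple-labelled libraries (SD, n = 3). It was lower in the double mutant than in N2 (log2 fold change -0.91 ± 0.086 SE, edgeR adjusted p = 3.2e-08), and its log2 fold change between the triple-labelled and daf-2 libraries was -0.10 (edgeR adjusted p = 0.34). spr-4 (WBGene00005009, I, 8103596 to 8109228) was lower in both spr groups, at -0.25 ± 0.044 against N2 in the double mutant and -0.21 ± 0.044 against daf-2 in the triple-labelled libraries. daf-2 itself (WBGene00000898, III, 2994514 to 3040846) had 94.7 ± 1.8 CPM in N2 and 86.6 ± 9.68 in the daf-2 mutant, a log2 difference of -0.13 (edgeR adjusted p = 0.098) that passed at -0.18 without daf-2 replicate 2 (edgeR adjusted p = 0.012). Its adjusted p ran from 0.012 to 0.62 over the alternatives other than the 1.5-fold test. hop-1 (WBGene00001985, I, 4208515 to 4210341), a presenilin gene, had 60 ± 0.802 CPM in N2 and 63.3 ± 0.496 in the double mutant (log2 fold change 0.08, edgeR adjusted p = 0.12). The labels give no alleles, and counts over a whole gene need not fall where a mutation leaves its transcript in place. The spr-3 level of the triple-labelled libraries therefore neither bears out nor excludes that part of their label.

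**Figure D1:**
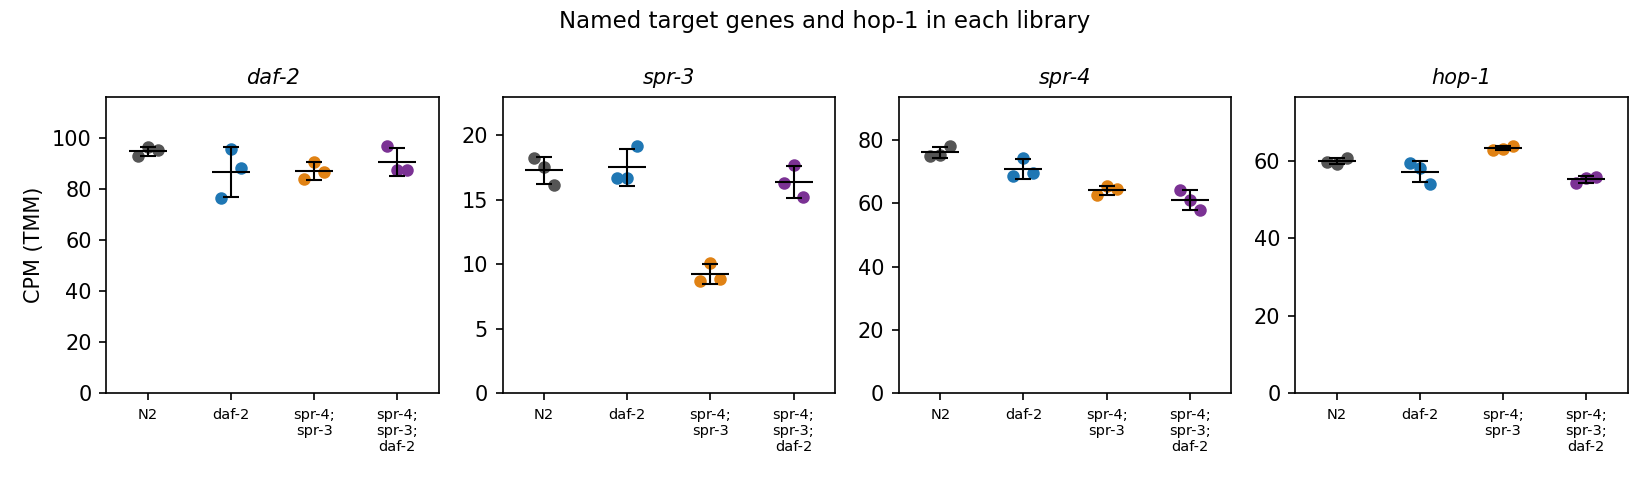
TMM-scaled CPM of daf-2, spr-3, spr-4 and hop-1 in each of the 12 libraries, by genotype. Points are libraries, bars give the mean and SD of 3, and each axis starts at 0. spr-3 had 9.22 CPM in the spr double mutant, 17.3 in N2 and 17.5 in daf-2.

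The comparison of daf-2 with N2 shows what differs with the insulin receptor mutation when both spr genes are intact. A difference in stage or strain between these groups would show here as well. Most targets that the transcription factor DAF-16 is known to raise were higher in daf-2. Among them sod-3, a mitochondrial superoxide dismutase, went from 3.16 ± 0.0836 to 26 ± 2.2 CPM (log2 fold change 3.04 ± 0.11), and the metallothionein mtl-1 from 11.9 ± 0.836 to 101 ± 2.48 CPM (3.07 ± 0.17). Of the sperm genes 37 of 41 and of the cuticle collagens 107 of 153 were lower, with the major sperm protein gene msp-36 at 12.9 ± 2.02 CPM in N2 and 0.273 ± 0.0717 in daf-2, and the collagen gene col-149 at 23.7 ± 4.19 and 0.463 ± 0.0904 (SD, n = 3). Large rises were seen in the saposin-like genes spp-9 (8.77 ± 0.54) and spp-12 (6.07 ± 0.38). Other large rises were scl-20 (5.42), icmt-1 (5.19), fipr-23 (4.94), pals-26 (4.35), dpy-14 (4.23) and fipr-26 (4.1). Other large falls were nsph-3.2 (-5.51), sqt-2 (-5.45), ssq-2 (-5.24), clec-10 (-5.10), msp-40 (-5.08) and msp-76 (-4.89).

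Of 26 measured targets raised by DAF-16, 22 rose and 1 fell over all genes tested (23 and 1 adjusted over the list alone), with a median log2 fold change of 1.79. Camera gave adjusted p = 2.66e-11 for this list, and adjusted p = 0.178 with an estimated correlation. dod-3 rose by 3.61 and nnt-1 by 3.09. Of 10 measured targets lowered in daf-2 through DAF-16, 6 fell and 2 rose (6 and 3 adjusted over the list alone). Camera gave adjusted p = 0.067 for that list, 0.0283 without a filter on low counts and 0.215 with an estimated correlation. Insulin-like peptide genes rose in 20 of 29 members and fell in 1 (21 and 1 adjusted over the list alone), with ins-10 at 4.09, camera adjusted p = 2.49e-06 and adjusted p = 0.0654 with an estimated correlation. FMRFamide-like neuropeptide genes rose in 20 of 30 members (22 adjusted over the list alone), with flp-34 at 1.66, camera adjusted p = 9.46e-06 and adjusted p = 0.178 with an estimated correlation. Antioxidant genes rose in 17 of 21 members and fell in 1 (17 and 1 adjusted over the list alone), gst-4 by 1.47, with camera adjusted p = 1.03e-05 and adjusted p = 0.189 with an estimated correlation. Innate immune effectors rose in 50 of 92 members and fell in 22 (55 and 22 adjusted over the list alone), with camera adjusted p = 0.000573 and adjusted p = 0.309 with an estimated correlation.

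Sperm genes fell in 37 of 41 members and rose in 2 (37 and 2 adjusted over the list alone), with a median of -4.77, camera adjusted p = 7.27e-17 and adjusted p = 0.189 with an estimated correlation. Many msp genes are near-identical copies, so their single values are uncertain. Cuticle collagens fell in 107 of 153 members and rose in 24 (108 and 24 adjusted over the list alone), with col-41 at -7.19 and col-50 at 6.66, camera adjusted p = 2.66e-11 and adjusted p = 0.245 with an estimated correlation. Pharynx genes fell in 11 of 13 members and rose in 2 (11 and 2 adjusted over the list alone), with phat-4 at -3.28, camera adjusted p = 0.000398 and adjusted p = 0.129 with an estimated correlation. Voltage-gated and leak ion channel genes fell in 16 of 35 members and rose in 2 (16 and 2 adjusted over the list alone), including the calcium channel gene egl-19 (-0.79 ± 0.076), with camera adjusted p = 0.0104 and adjusted p = 0.245 with an estimated correlation. In lipid metabolism 19 of 32 genes rose and 7 fell (19 and 7 adjusted over the list alone). The lipase gene lipl-1 rose by 3.30 on the log2 scale and the desaturase gene fat-7 fell by 2.42. Camera gave adjusted p = 0.0112 for that list, and adjusted p = 0.245 with an estimated correlation. The share of counts on ribosomal RNA genes was 0.166% ± 0.0158 in daf-2 against 0.0391% ± 0.0038 in N2, and rrn-3.1 was higher by 2.22. The share was 0.0405% ± 0.0049 in the spr double mutant. Since the libraries came from an mRNA kit, a difference in preparation cannot be told apart from a daf-2 effect on this share. In all, 8560 genes passed edgeR's quasi-likelihood test, 4319 higher and 4241 lower in daf-2, and 2679 of them changed over 2-fold, 1342 higher and 1337 lower. With a test against a 1.5-fold change, 2810 genes passed.

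The comparison of the triple-labelled libraries with daf-2 shows what differs with the spr label in daf-2 animals. Most sperm genes were higher with the label: smz-1 rose by 3.23 ± 0.16, ssq-4 by 3.02 and the major sperm protein genes msp-40, msp-57 and msp-51 by 3.03, 2.94 and 2.85, beside spsp-1 (3.18) and nsph-3.2 (2.88). fog-3, which directs germ cells to the sperm fate, went from 0.901 ± 0.288 to 7.92 ± 0.549 CPM (3.12 ± 0.18). It did not follow the sperm genes in the spr double mutant, where it was higher than in N2 (fog-3 log2 fold change 1.55) while 37 of 41 sperm genes were lower. Several genes of neuronal signalling were also higher, including the sodium leak channel gene nca-2 (1.77 ± 0.14) and ric-19 (1.40 ± 0.097). The lysozyme gene ilys-5 fell from 124 ± 14.3 to 1.76 ± 0.46 CPM (-6.14 ± 0.15), and the prolyl isomerase gene pinn-4 from 40.3 ± 3.09 to 3.12 ± 0.332 CPM (-3.69 ± 0.096). Other large falls were the protease gene cpr-5 (-2.97), col-135 (-2.91), col-138 (-2.77), srh-237 (-2.53) and cls-3 (-2.24). col-73 fell by 3.56 (edgeR adjusted p = 0.021), a call lost without triple-labelled replicate 1 (edgeR adjusted p = 0.062), 2 (0.051) or 3 (0.064).

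Voltage-gated and leak ion channel genes rose in 20 of 35 members and fell in 1 (22 and 1 adjusted over the list alone), with a median of 0.40, camera adjusted p = 6.07e-05 and adjusted p = 0.119 with an estimated correlation. Synaptic vesicle and release genes rose in 15 of 24 and fell in 2 (15 and 2 adjusted over the list alone), including rab-3 (0.67), tom-1 (0.58) and unc-31 (0.56), with camera adjusted p = 0.00558 and adjusted p = 0.234 with an estimated correlation. Glutamate signalling genes rose in 14 of 25 members (14 adjusted over the list alone), such as the receptor gene glr-1 (1.17) and glt-5 (1.1), with camera adjusted p = 0.00718 and adjusted p = 0.119 with an estimated correlation. Acetylcholine signalling genes rose in 8 of 23 members and fell in 1 (7 and 1 adjusted over the list alone), including the receptor subunit genes unc-29 (1.15) and unc-38 (1.12), with camera adjusted p = 0.00558 and adjusted p = 0.119 with an estimated correlation. GABA signalling genes rose in 6 of 13 members (6 adjusted over the list alone), including lgc-38 (1.00) and unc-49 (0.68), with camera adjusted p = 0.0245 and adjusted p = 0.123 with an estimated correlation. FMRFamide-like neuropeptide genes rose in 16 of 30 members (18 adjusted over the list alone), including flp-8 (0.62), with camera adjusted p = 0.000732 and adjusted p = 0.234 with an estimated correlation. Monoamine signalling genes rose in 4 of 24 members and fell in 2, with camera adjusted p = 0.417 and fry adjusted p = 0.00204. Insulin-like peptide genes rose in 7 of 29 and fell in 1, with camera adjusted p = 0.263 and fry adjusted p = 0.00398. In other tissues, 6 of 20 muscle genes and 5 of 13 pharynx genes rose and 0 fell (camera adjusted p = 0.123 and 0.11, fry adjusted p = 0.0794 and 0.00148). In whole animals a change in tissue makeup was not separated from a change within neurons.

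Sperm genes rose in 37 of 41 members and fell in 1 (37 and 1 adjusted over the list alone), with a median of 2.67, camera adjusted p = 3.05e-12 and adjusted p = 0.234 with an estimated correlation. Oocyte and eggshell genes fell in 20 of 22 members (20 adjusted over the list alone), including the yolk receptor gene rme-2 (-0.53) and the chitin synthase gene chs-1 (-0.51), with camera adjusted p = 1.59e-11 and adjusted p = 0.119 with an estimated correlation. Of 6 vitellogenin genes 4 fell (4 adjusted over the list alone), vit-1 by 1.35, with camera adjusted p = 0.0086 and adjusted p = 0.346 with an estimated correlation. Such tallies weigh each gene alike. The share of all counts on the 6 genes together was 9.21% ± 0.418 in daf-2 and 8.94% ± 0.354 in the triple-labelled libraries. Targets raised by DAF-16 rose in 11 of 26 members and fell in 2 (11 and 2 adjusted over the list alone), with dod-6 at 0.97 and mtl-1 at 0.82. Camera gave adjusted p = 0.0802, with 0.0412 without daf-2 replicate 1, 0.0457 without spr double mutant replicate 2, and 0.0169 to 0.157 over the alternatives. Cuticle collagens rose in 40 of 153 members and fell in 29 (38 and 29 adjusted over the list alone), with a median of 0.03 and a mean of -0.27, and camera gave adjusted p = 0.76. The ribosomal RNA share was 0.0431% ± 0.0025 in the triple-labelled libraries against 0.166% ± 0.0158 in daf-2. A difference in the preparation of the daf-2 libraries would enter every comparison with them and was not tested. In all, 7410 genes passed, 4115 higher and 3295 lower, and 1493 changed over 2-fold, of which 1209 were higher. Against a 1.5-fold change 1216 genes passed.

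**Figure D2:**
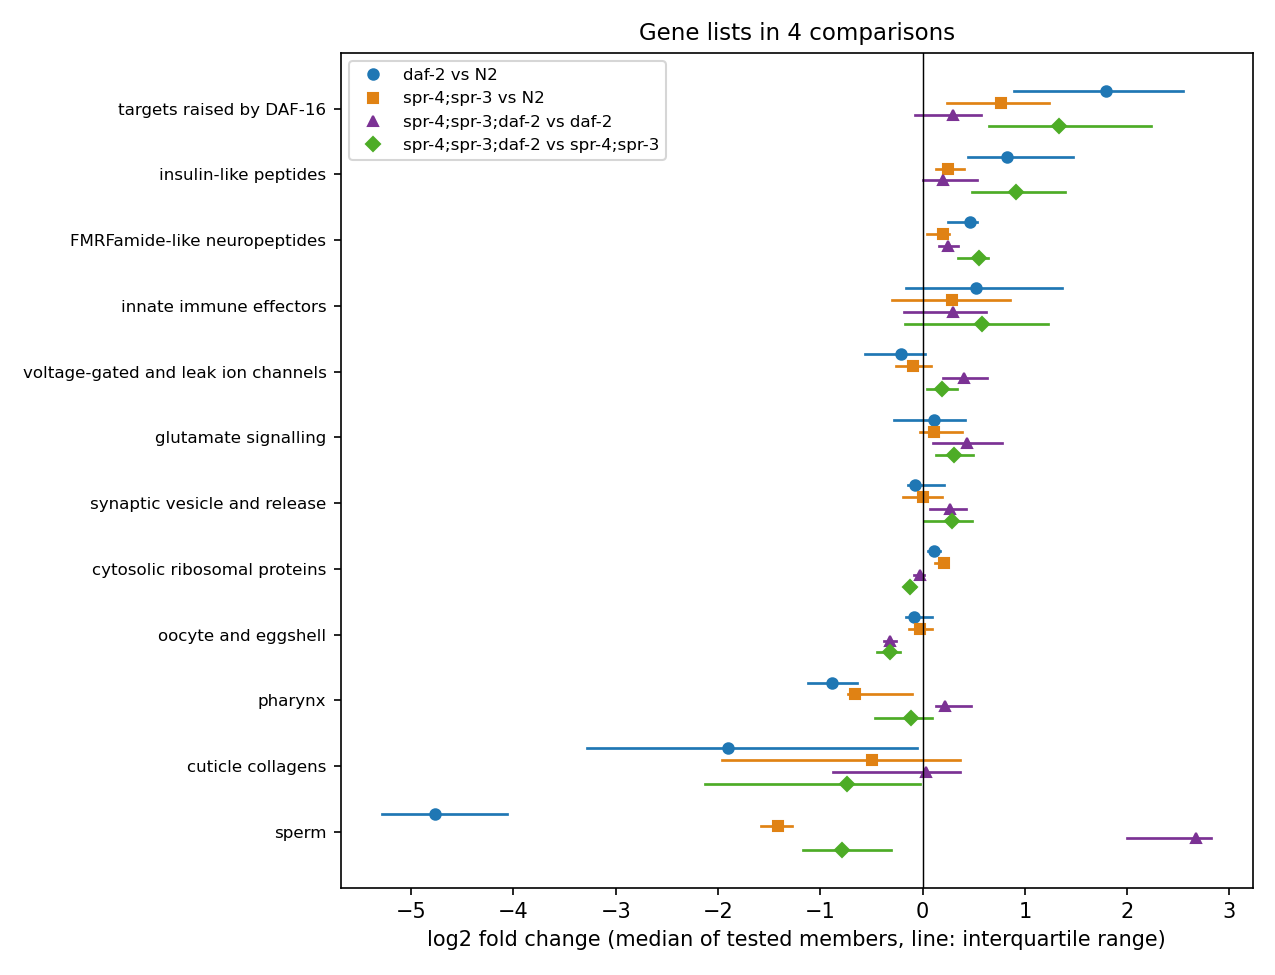
Median log2 fold change (symbols) and interquartile range (lines) of the tested members of 12 gene lists in 4 comparisons. Sperm genes had medians of -4.77 in daf-2 against N2 and 2.67 in the triple-labelled libraries against daf-2, and targets raised by DAF-16 had medians of 1.79 and 0.30.

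The comparison of the spr double mutant with N2 shows what differs with the spr mutations when daf-2 is intact, and differences in stage or strain are not separated here either. unc-38, a nicotinic acetylcholine receptor subunit gene, went from 1.61 ± 0.277 to 19 ± 0.349 CPM (log2 fold change 3.57 ± 0.12). The neurabin gene nab-1 went from 9.55 ± 0.146 to 77.1 ± 3.68 CPM (3.01 ± 0.061) and the kinase gene mapk-15 from 2.54 ± 0.559 to 16 ± 0.478 CPM (2.70 ± 0.14). Other large rises were icmt-1 (4.90), spp-9 (4.16), dpy-14 (3.17), spp-12 (2.98) and pals-39 (2.72). Falls were seen in the cuticle collagen genes col-10 (-3.01), col-167 (-2.97), col-117 (-2.62), rol-8 (-2.55) and col-3 (-2.42), with lpr-3 (-2.87), the moulting gene mlt-11 (-2.47) and dao-2 (-2.38).

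Targets raised by DAF-16 rose in 21 of 26 members and fell in 1 (21 and 1 adjusted over the list alone), with a median of 0.77, camera adjusted p = 1.02e-05 and adjusted p = 0.473 with an estimated correlation. Targets lowered in daf-2 through DAF-16 rose in 6 of 10 members and fell in 4 (6 and 4 adjusted over the list alone). Their median was 0.39 and camera gave adjusted p = 0.658. Cytosolic ribosomal protein genes rose in 55 of 81 members and fell in 4 (60 and 5 adjusted over the list alone), with rps-27 at 0.37 and rla-0 at 0.34, camera adjusted p = 1.48e-05 and adjusted p = 0.757 with an estimated correlation. Sperm genes fell in 37 of 41 members and rose in 1 (37 and 2 adjusted over the list alone), with a median of -1.41, camera adjusted p = 8.53e-10 and adjusted p = 0.473 with an estimated correlation. Cuticle collagens fell in 72 of 153 members and rose in 42 (78 and 43 adjusted over the list alone). Their camera adjusted p was 0.00357, with adjusted p = 0.752 with an estimated correlation. It was 0.103 on total counts, 0.0817 with at least 1 CPM in 6 libraries, and 0.00129 to 0.103 over these and the other alternatives. Pharynx genes fell in 7 of 13 members (8 adjusted over the list alone), phat-5 by 3.31, with camera adjusted p = 0.00138 and adjusted p = 0.321 with an estimated correlation. Genes of the organelle unfolded protein response fell in 9 of 16 members and rose in 1 (9 and 1 adjusted over the list alone), including pdi-2 (-0.67), with camera adjusted p = 0.0078 and adjusted p = 0.473 with an estimated correlation. Synaptic vesicle and release genes rose in 7 of 24 members and fell in 6 (7 and 7 adjusted over the list alone), and camera gave adjusted p = 0.84. Ion channel genes rose in 4 of 35 members and fell in 5 (3 and 4 adjusted over the list alone), and nca-2 rose by 1.33 and ccb-1 by 1.94. In all, 7324 genes passed, 3879 higher and 3445 lower, and 1444 changed over 2-fold, 647 higher and 797 lower. With total counts as the only scaling 35% of the calls were higher, against 53.0% with TMM, and 1135 genes passed against a 1.5-fold change.

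The daf-2 effect in animals with the spr label compared the triple-labelled libraries with the spr double mutant. Their spr-3 levels differed, so a difference in spr genotype between these groups cannot be told apart from a daf-2 effect. Most targets raised by DAF-16 were again higher: sod-3 by 2.36 ± 0.11, mtl-1 by 2.56 ± 0.16 and the long noncoding RNA tts-1 by 2.65 ± 0.21. The lipase gene lipl-1 rose by 3.41 and dct-8 by 3.12, beside scl-20 (4.59), spp-9 (4.43), fipr-23 (3.80), spp-12 (3.64), pitr-4 (3.03) and ugt-36 (3.03). ilys-5 fell by 7.82 on the log2 scale, and col-73 (-5.95), col-138 (-5.51), dpy-5 (-4.46), clec-10 (-4.44), col-149 (-4.13), col-133 (-4.12) and col-135 (-4.01) fell with it. spr-3 was higher in the triple-labelled libraries by 0.83 ± 0.086 (edgeR adjusted p = 6.9e-08) and hop-1 fell by 0.20.

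Of the targets raised by DAF-16, 21 of 26 rose and 2 fell (21 and 2 adjusted over the list alone), with camera adjusted p = 7.57e-10 and adjusted p = 0.159 with an estimated correlation. Targets lowered in daf-2 through DAF-16 fell in 7 of 10 members (8 adjusted over the list alone), with camera adjusted p = 0.000264 and adjusted p = 0.05 with an estimated correlation. FMRFamide-like neuropeptide genes rose in 26 of 30 members (26 adjusted over the list alone), with camera adjusted p = 1e-08 and adjusted p = 0.0877 with an estimated correlation. Insulin-like peptide genes rose in 21 of 29 and fell in 1 (21 and 1 adjusted over the list alone), with camera adjusted p = 7.58e-07 and adjusted p = 0.05 with an estimated correlation. Synaptic vesicle and release genes rose in 15 of 24 and fell in 2 (15 and 2 adjusted over the list alone), with snt-1 at 0.70, camera adjusted p = 0.0049 and adjusted p = 0.25 with an estimated correlation. Oocyte and eggshell genes fell in 21 of 22 members and rose in 1 (21 and 1 adjusted over the list alone), with camera adjusted p = 4.44e-09 and adjusted p = 0.159 with an estimated correlation. Nuclear oxidative phosphorylation genes fell in 27 of 48 members (27 adjusted over the list alone), nduf-2.2 by 0.28, with camera adjusted p = 2.79e-05 and adjusted p = 0.463 with an estimated correlation. Vitellogenin genes fell in 5 of 6 members (6 adjusted over the list alone), with vit-1 at -1.89, camera adjusted p = 0.000264 and adjusted p = 0.232 with an estimated correlation. Their share of all counts was 8.94% ± 0.354 in the triple-labelled libraries against 10.4% ± 0.148 in the double mutant. Sperm genes fell in 23 of 41 members and rose in 5 (24 and 5 adjusted over the list alone), with a median of -0.79, camera adjusted p = 0.00102 and adjusted p = 0.523 with an estimated correlation. In all, 7777 genes passed, 4069 higher and 3708 lower, and 1625 changed over 2-fold, 1159 higher and 466 lower. With total counts 68.1% of the calls were higher, against 52.3% with TMM, and 1545 genes passed against a 1.5-fold change.

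**Figure D3:**
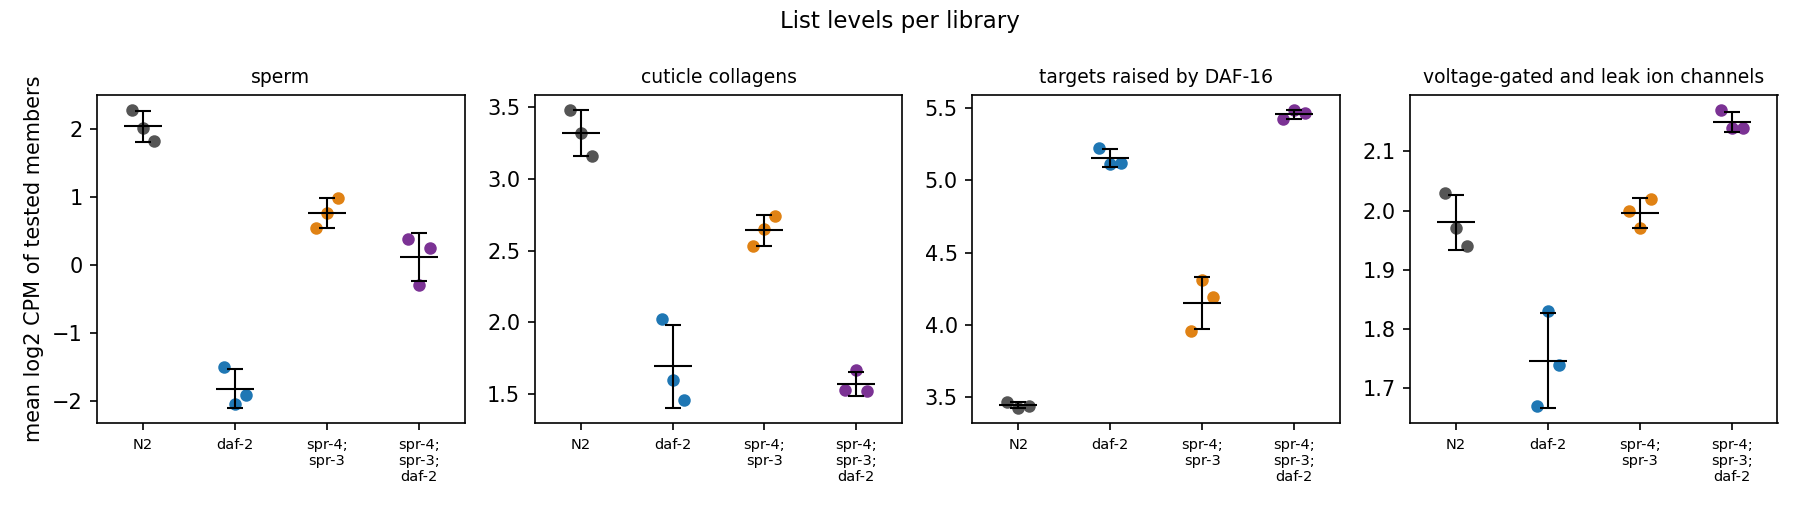
Mean log2 CPM of the tested members of 4 lists in each library, by genotype, with the mean and SD of 3 libraries. The axes do not start at 0. Sperm levels ran from 1.83 to 2.28 in N2, from -2.05 to -1.50 in daf-2 and from -0.29 to 0.38 in the triple-labelled libraries.

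Between the triple-labelled libraries and N2, most DAF-16 targets and neuropeptide genes were higher and most cuticle collagens lower. mtl-1 rose by 3.89 ± 0.17, sod-3 by 2.80 ± 0.11 and the heat shock gene hsp-70 by 3.75 ± 0.19. ilys-5 had 664 ± 31.5 CPM in N2 and 1.76 ± 0.46 in the triple-labelled libraries (-8.56 ± 0.15), and the collagen genes dpy-5 (-6.73), dpy-13 (-6.26) and dpy-4 (-5.31) fell. Of the DAF-16 targets 24 of 26 rose and 1 fell (25 and 1 adjusted over the list alone), with camera adjusted p = 7.64e-09 and adjusted p = 0.186 with an estimated correlation. FMRFamide-like neuropeptide genes rose in 29 of 30 members (29 adjusted over the list alone), with camera adjusted p = 2.41e-07 and adjusted p = 0.186 with an estimated correlation. Insulin-like peptide genes rose in 25 of 29 members (25 adjusted over the list alone), with camera adjusted p = 2.68e-06 and adjusted p = 0.0698 with an estimated correlation. Cuticle collagens fell in 96 of 153 members and rose in 37 (96 and 37 adjusted over the list alone), with camera adjusted p = 6.57e-07 and adjusted p = 0.39 with an estimated correlation. In all, 10829 genes passed, 5586 higher and 5243 lower, and 3404 changed over 2-fold, 2196 higher and 1208 lower. Against a 1.5-fold change 3835 passed, 68.1% of them higher.

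The interaction tests whether the daf-2 effect differs between libraries with and without the spr label. That reading requires the same spr mutations in both spr-labelled groups, which their spr-3 levels leave open. Unequal stages of the groups would enter the interaction too: of 16 moulting genes 10 had a positive one and 1 a negative one. The interaction was positive, that is, the effect was higher in libraries with the spr label, for sqt-2 (4.75 ± 0.25) and the sperm genes msp-57 (4.40), msp-40 (4.36), ssq-4 (4.31), msp-36 (4.29) and msp-51 (4.25). It was negative for ilys-5 (-5.40 ± 0.18), spp-9 (-4.34), icmt-1 (-3.97), pinn-4 (-3.79), dpy-14 (-3.44) and cls-3 (-2.97). The call for spp-9 (edgeR adjusted p = 0.015) was lost without N2 replicate 1 (-3.99, edgeR adjusted p = 0.061). Sperm genes had a positive interaction in 38 of 41 members (38 adjusted over the list alone), with a median of 4.07, camera adjusted p = 1.36e-23 and adjusted p = 0.118 with an estimated correlation. Ion channel genes had a positive interaction in 18 of 35 members and a negative one in 1 (18 and 1 adjusted over the list alone), including egl-2 (1.12) and shl-1 (0.99), with camera adjusted p = 1.75e-05 and adjusted p = 0.118 with an estimated correlation. Synaptic vesicle and release genes had a positive one in 9 of 24 members (10 adjusted over the list alone), rab-3 at 1.01 and snt-1 at 0.78, with camera adjusted p = 0.00324 and adjusted p = 0.206 with an estimated correlation. Ribosomal protein genes had a negative one in 40 of 81 members (49 adjusted over the list alone), with camera adjusted p = 5.76e-09 and adjusted p = 0.569 with an estimated correlation. Oocyte and eggshell genes had a negative one in 18 of 22 members (19 adjusted over the list alone), with camera adjusted p = 3.61e-09 and adjusted p = 0.131 with an estimated correlation. Of 26 DAF-16 targets 12 had a negative interaction and 1 a positive one (12 and 1 adjusted over the list alone), including dod-3 (-1.35) and ftn-1 (-1.03), with camera adjusted p = 0.00302 and adjusted p = 0.482 with an estimated correlation. In all, 4523 genes passed, 2224 positive and 2299 negative. Of those over 2-fold 1063 were positive and 370 negative, and of 970 that passed against a 1.5-fold change 76% were positive. With total counts the median of all genes moved from 0.006 to 0.128 and 77.5% of the calls were positive, against 49.2% with TMM.

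Across 15764 genes, which are not independent replicates, the daf-2 effects without and with the spr label, taken from different libraries, had Pearson r = 0.621 and Spearman rho = 0.594, against a mean r of 0.003 in 20 simulations of unchanged groups. Without a filter on low counts r was 0.333, and with at least 1 CPM in 6 libraries 0.721. Of the genes called in both, 4745 had the same sign and 369 opposite signs. The differences with the spr label in the 2 daf-2 backgrounds had r = 0.164 and rho = 0.296, against a simulated mean r of 0.005, with 3389 genes of the same sign and 861 of opposite signs. That r was 0.062 without a filter, 0.376 with at least 1 CPM in 6 libraries and 0.269 in fits of only the groups compared. The effects of daf-2 and of the spr double mutant against the same N2 libraries had r = 0.684, against 0.475 simulated with unchanged groups. Their covariance was 0.517 against 0.019 simulated. Among genes called in both, 2356 were higher in both against 1063 for independent lists, and 2533 lower in both against 927. Of the genes lowered over 2-fold in daf-2, 648 of 1337 (48.5%) were higher again in the triple-labelled libraries than in daf-2 and 132 fell further. Of those raised over 2-fold, 244 of 1342 (18.2%) were lower again and 473 rose further. Over all calls 1808 genes moved back and 2677 moved on in the same direction, with 728 higher and then lower against 903 for independent lists, and 1080 lower and then higher against 1107. Over all calls moving back thus did not exceed independent lists. Genes higher in both numbered 1515 against 1127, and those lower in both 1162 against 886. These comparisons share the daf-2 libraries: r was -0.339 against -0.513 simulated and the covariance -0.279 against -0.02 simulated. Groups of 3 could not be split into parts of at least 2 libraries, so part of any covariance beyond the simulated one may come from the shared libraries.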

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

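The moult-marker tests of daf-2 and of the spr double mutant against N2, the test of the scaling of sperm genes, the tests of linkage within single chromosomes and the test of the spr-3 read count were chosen only after the results they bear on had been seen. The daf-2 effect differed with the spr label, by the interaction's own test, for 4523 genes. A difference in spr genotype between the spr double mutant and the triple-labelled libraries would enter this count as well. Unequal stages of the groups would do so too. In 100 random regroupings of the 12 libraries, the real one included, 1 gave as many and the highest other value was 270. Regroupings mix genotypes, which widens the spread within groups, and 92 of the 100 called 0 genes, so this share says little about the count. By gene the log2 interaction was 4.75 for sqt-2, 4.40 for msp-57, 4.36 for msp-40, 4.31 for ssq-4, 4.29 for msp-36 and 4.25 for msp-51. It was -5.40 for ilys-5, -4.34 for spp-9, -3.97 for icmt-1, -3.79 for pinn-4, -3.44 for dpy-14, -2.97 for cls-3 and 0.81 for spr-3. The call for spp-9 was lost without N2 replicate 1 (-3.99, edgeR adjusted p = 0.061).

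Camera called 15 lists for the interaction, none of them with an estimated correlation. The medians were 4.07 for sperm, 0.85 for pharynx, 0.47 for ion channels, 0.45 for GABA signalling, 0.44 for acetylcholine signalling, 0.31 for cuticle collagens, 0.21 for synaptic release and 0.13 for muscle. They were -0.11 for nuclear oxidative phosphorylation, -0.12 for antioxidant genes, -0.23 for ribosomal proteins, -0.26 for oocyte and eggshell, -0.37 for targets raised by DAF-16, -0.66 for embryo and -0.76 for vitellogenins. On total counts camera's adjusted p was 0.238 for collagens and 0.171 for oxidative phosphorylation, whose median was then 0.01. With at least 1 CPM in 6 libraries it was 0.0672 for both embryo genes and collagens, and without daf-2 replicate 3 it was 0.0887 for collagens and 0.221 for muscle. Muscle also lost its call without N2 replicates 1 (0.056) and 3 (0.0659), spr double mutant replicates 2 (0.0583) and 3 (0.0892) and triple-labelled replicate 1 (0.164). Over the alternatives other than the estimated correlation, adjusted p ran from 0.000107 to 0.238 for collagens, 0.00577 to 0.221 for muscle and 0.000139 to 0.0672 for embryo genes. In 9 of the 100 regroupings camera called at least 15 lists, with a highest other value of 19. Since regroupings mix genotypes that still differ, this share neither bears out nor excludes chance for the number of lists.

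For single pairs of groups the 6 libraries make 10 splits, too few for a share under 0.05. The real splits, 1 of 10 each, called 8560 genes for daf-2 against N2, 7410 for the triple-labelled libraries against daf-2, 7324 for the spr double mutant against N2, 7777 for the triple-labelled libraries against the double mutant and 10829 for these against N2, and the highest other split called 0 in each. Camera's lists behaved differently: in the first 3 of these comparisons splits that called 0 genes called as many lists. In the same order the real counts of lists were 16, 11, 10, 17 and 16, the highest others 18, 16, 10, 15 and 12, and the splits with as many lists 2, 4, 2, 1 and 1. In the first 3 the number of lists does not set the real split apart from the others. In the last 2 no other split called as many, at a share that 10 splits cannot bring under 0.05. The 1808 genes that moved back were reached in 2 of 100 regroupings (highest other 2233). In 96 of the 100 the number was 0, so this share says little about the moving back either. Regroupings reached the correlation of the daf-2 effects (0.621) in 9 of 100 (highest other 0.768) and that of the spr effects (0.164) in 36 of 100 (highest other 0.799). Regrouped libraries still differ by genotype, so these shares do not give the values of unchanged groups. Simulated unchanged groups gave a mean r of 0.003 and 0.005, which argues against independent noise of single libraries as the source of the correlations.

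The mean levels of sperm genes and cuticle collagens were highest in N2, and most sperm transcripts were higher in the triple-labelled libraries than in daf-2 while most egg transcripts were lower. For the rise of sperm genes, a few abundant genes distorting the scaling is argued against, since at least 37 of 41 were higher in the triple-labelled libraries than in daf-2 under each of 3 scalings. That test did not cover cuticle or egg genes, and the collagen call in the spr double mutant against N2 was lost on total counts (camera adjusted p = 0.103). The mutants may have been at a later stage than N2 when collected: of 16 moulting genes 11 were lower and 2 higher in daf-2 than in N2. In the spr double mutant 12 were lower and 1 higher, and in the triple-labelled libraries 12 were lower and 4 higher than in N2. A direct effect on the cuticle would give such values as well. Whether the triple-labelled animals were younger than daf-2 animals was not decided: 5 of the 16 were higher and 5 lower than in daf-2. A minority higher had been set in advance as evidence against a younger stage, but the exact 95% interval of the share higher reached 58.7%. That interval treats the genes as independent, which they need not be. An effect of the mutations on germ line or cuticle at an equal stage stays open as a hypothesis and was not tested.

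Over 2-fold changes of the same sign in both spr comparisons were found for 376 genes, and variants linked to spr-4 or spr-3 could be their source. Within 2 Mb of these loci the odds ratio was 0.819 (95% interval 0.53 to 1.22, exact Fisher p = 0.353), and against the rest of the same chromosomes 1.01 (0.612 to 1.64), which does not decide on an excess there. A linked variant that acts only on genes this close does not account for the 349 genes that lay elsewhere. One that acts on distant genes cannot be seen by position and was not tested. Genes near spr-4 such as fog-3, hsp-70 and fipr-26 stay open. For the 1076 genes changed alike in both daf-2 comparisons, the odds ratio within 2 Mb of daf-2 was 0.564 (95% interval 0.363 to 0.839). An odds ratio of at most 1 had been set in advance as evidence against linkage, but chromosome III as a whole held few such genes, 80 of 2395. Against the rest of that chromosome the odds ratio was 1.32 (0.787 to 2.17), so linkage cannot be told apart from other causes for the 26 genes near daf-2. A linked variant that acts only on genes this close does not account for the 1050 that lay elsewhere, and one that acts on distant genes was not tested. Effects of the mutations themselves, and unlinked strain differences, stay open and were not tested.

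The spr-3 transcript was lower in the spr double mutant and not detectably lower in the triple-labelled libraries. Too few reads is argued against, since the lowest count on spr-3 was 258. Of 288 genes changed over 2-fold in the double mutant against N2 and not called in daf-2 against N2, 86.8% had the same sign in the triple-labelled libraries against daf-2. That argues against triple-labelled animals that were the same as the daf-2 group. Such a share had been set in advance as evidence against animals that lack the spr mutations altogether. Strain background or a stage shared by the 2 spr-labelled groups would give it as well, so it does not exclude such animals. Another spr-3 allele, animals that carry the spr-4 mutation alone, or animals that lack both but share other differences stay open, since no value here separates them.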

How the results depend on the processing

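Every alternative was chosen before the data were examined, and none of those run reversed the sign of a called change in a named gene. On total counts the share of calls that were higher went from 53 to 35% for the spr double mutant against N2, the share of interaction calls that were positive from 49.2 to 77.5%, and the median interaction of nuclear oxidative phosphorylation genes from -0.11 to 0.01. Against a 1.5-fold change, a stricter null by construction, 2810 genes passed for daf-2 against N2, 1216 for the triple-labelled libraries against daf-2, 1135 for the spr double mutant against N2, 1545 for the triple-labelled libraries against the double mutant, 3835 for these against N2, 970 for the interaction, and 456 moved back. With an estimated correlation camera called 0 lists in each of the 6 comparisons. Without a filter on low counts the correlation of the daf-2 effects was 0.333 and of the spr effects 0.062, and with at least 1 CPM in 6 libraries 0.721 and 0.376, with 1170 genes moving back (fewer genes are tested). Fits of only the groups compared gave 0.269 for the spr effects, and the cause was not tested. The other counts stayed within 1.5 times their values under RLE, total counts, both filters, DESeq2, limma-voom and the replicate block, which gave 4316 interaction genes.

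Leaving out each library in turn gave 7540 to 8633 genes for daf-2 against N2, 6324 to 7508 for the triple-labelled libraries against daf-2, 5845 to 7646 for the double mutant against N2, 6579 to 7924 for the triple-labelled libraries against it, 10009 to 11101 against N2, and 3585 to 4780 for the interaction. Lists numbered 15 to 17, 10 to 15, 9 to 11, 15 to 18, 14 to 16 and 13 to 17. The correlations ran from 0.574 to 0.627 and 0.114 to 0.191, and 1568 to 1855 genes moved back. Over 775 results of named genes, 351 of 9300 values without a library lost a call and 7 gained one, and 483 of 6746 other values lost one, 384 of them in the 1.5-fold test, and 12 gained one. Simulated 1.5-fold interactions were recovered in 37.9% of cases, so small ones can be missed in this design.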

Other observations

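Autophagy genes rose in 14 of 27 members and fell in 1 in daf-2 against N2 (14 and 2 adjusted over the list alone), epg-2 by 1.56 and sqst-1 by 1.09, with camera adjusted p = 0.0173 and adjusted p = 0.343 with an estimated correlation. Germline genes fell in 13 of 20 members there (13 adjusted over the list alone), glp-1 by 0.35, with camera adjusted p = 0.0112 and adjusted p = 0.178 with an estimated correlation. Muscle genes fell in 13 of 20 members (14 adjusted over the list alone), tni-1 by 1.24, with camera adjusted p = 0.000639 and adjusted p = 0.364 with an estimated correlation. Intestine genes fell in 13 of 20 members and rose in 5 (13 and 5 adjusted over the list alone), with the peptide transporter gene pept-1 at -2.17, camera adjusted p = 0.0173 and adjusted p = 0.364 with an estimated correlation. Of 12 mitochondrially encoded protein genes none was called in daf-2 against N2, with a median of -0.35. Insulin/IGF-1 signalling components rose in 8 of 19 members and fell in 8 (8 and 8 adjusted over the list alone), with the kinase gene akt-2 at 1.38, and camera gave adjusted p = 0.949.

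unc-38 (I, 4897620 to 4900974) and icmt-1 (I, 4901918 to 4903264), which lie beside each other, were both lowest in N2. unc-38 had 1.61, 10.8, 19 and 23.6 CPM in N2, daf-2, the spr double mutant and the triple-labelled libraries, and icmt-1 had 0.259, 9.47, 7.75 and 18.2. nab-1 (I, 4229570 to 4236115) had 9.55, 11.4, 77.1 and 34 CPM in the same order, and mapk-15 had 2.54, 2.25, 16 and 14. Presenilin pathway genes fell in 7 of 10 members in the triple-labelled libraries against daf-2 (8 adjusted over the list alone), sel-12 by 0.37, with camera adjusted p = 0.0086 and adjusted p = 0.119 with an estimated correlation.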
